A study of Rattus norvegicus with 6 samples.

How the data were processed

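Liver RNA from 6 adult Sprague Dawley rats was hybridised to 6 arrays, 3 from offspring of males made hyperglycaemic with streptozotocin (STZ-O) and 3 from offspring of males that received citrate buffer (CB-O). Streptozotocin is a compound that kills insulin-producing beta cells and raises blood glucose. Per the labels' protocols, 1 animal per litter entered each test, sex was not distinguished, and the rats ate chow and were killed fed, with tissue frozen in liquid nitrogen and total RNA taken up in Trizol. The arrays were the Affymetrix rat transcriptome array (RTA-1_0), a 1-colour design in which biotin-labelled cDNA is read from many probes summarised as 1 probe set per transcript.

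The authors deposited log2 expression values, 1 per probe set and array, in a table of 70580 probe sets. Per the submitters' processing notes, Affymetrix Expression Console 1.4.1 and the robust multi-array average (RMA) were used; their parameters, the annotation and the genome build are not given in the sources used here, so no coordinates are printed. RMA subtracts background, forces the arrays towards a common distribution and fits 1 value per probe set. It removes differences in overall brightness between arrays and compresses fold changes of dim probe sets. The column medians lay between 5.77 and 5.82, so scale and centring were alike on all 6 arrays, and each column held 1 array on an absolute log2 scale, with no ratio to a reference. Scanner intensities were not used here.

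Control probe sets were left out before testing: 23 background, 155 ERCC spike-in, 1153 negative, 399 positive and 8 other controls, which left 68842 probe sets. The table carries no detection call. As a guide to brightness, the median over negative controls was 5.51 with a 95th percentile of 8.26, and the median over the tested probe sets was 5.79. Through the platform annotation, 23446 probe sets had 1 gene symbol, 505 had several and 44891 had none here. The Entrez identifiers of 22077 single-symbol probe sets were found in a reference gene set. Their symbols were taken from it unless malformed there. Each of 22093 genes was represented by its probe set with the highest mean over all 6 arrays, a choice blind to group; 1182 genes had more than 1 such probe set. Probe sets of near-identical relatives (Mx1 and Mx2, Scd and Scd2, Adh, Akr1c, Cyp, haemoglobin and RT1 genes) can share hybridisation, so values for these are uncertain as to which relative they measure.

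Differences are STZ-O minus CB-O on the log2 scale. They were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 on all 6 arrays, with no covariate, and adjusted by Benjamini-Hochberg over probe sets or over genes, with 0.05 as the threshold. The ± values beside differences are limma's moderated standard errors, and those beside group means are SDs. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 31 lists with at least 5 measured members. Camera with an estimated correlation and limma's fry were run beside it; fry asks whether the genes of a list move on balance one way (or, in its mixed form, in either direction) without comparing them with other genes. A list's level per array is the mean, over its genes, of the deviation from each gene's mean over the 6 arrays. Levels of the groups were compared by an exact two-sided permutation test, which with 3 arrays against 3 cannot give a p below 0.1. Limma's p-values for single genes measure the spread between these 3 arrays per group, each from 1 animal, and the number of arrays limits their precision. Camera compares a list's genes with all other genes. At the preset correlation its p does not measure the spread between animals. The estimated correlation was run on all 6 arrays only, so list calls in the other fits are at the preset correlation.

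The sample groups, the tests, the gene lists, the naming rule and the alternatives were fixed before the data were examined. The 32 lists held 567 entries, of which 517 were measured. They covered lipid handling (fatty acid and triglyceride synthesis, fatty acid oxidation, cholesterol synthesis, lipoproteins and lipid droplets, bile acids), glucose handling (gluconeogenesis, glycolysis, insulin and growth hormone signalling), stress (acute phase, interferon, unfolded protein response, oxidative stress, xenobiotic metabolism), epigenetic enzymes and imprinted genes, sex (Y-linked, X-inactivation, male-biased and female-biased genes), time (clock and immediate early genes), tissue state (ribosomal proteins, oxidative phosphorylation, cell cycle) and cell types (hepatocyte, Kupffer, stellate, endothelial, cholangiocyte, lymphocyte and neutrophil, red cell, and adipocyte with pancreas and muscle). The X-inactivation list was too small to test, and its gene was not analysed here. Named genes were the 15 highest and lowest past the adjusted threshold; with fewer than 20 such genes, the 12 highest and 12 lowest by moderated t among genes with a fold of at least 1.5 and a mean at or above the median of all genes; up to 4 members of each list with the smallest p; and sex-linked genes. Provisional symbols stayed in the ranking unnamed. Any other gene was chosen after its values were seen, and is named as such.

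The fit was tested on simulated data for this comparison, with 200 of 22093 genes changed in each of 20 runs. It recovered 73.5% of genes changed 1.5-fold, 93.7% of those changed 2-fold and 99.5% of those changed 4-fold, with 4.81% of calls false. These rates hold for 200 changed genes, since more calls ease the Benjamini-Hochberg cut, and for noise drawn from the observed variances. In the data 0 genes passed, and Plaat1, at 2.21-fold, had a limma adjusted p of 0.517. The rates therefore do not show that few genes changed. A simulated list of 20 genes shifted by 0.2 was called in 20 of 20 runs and an unshifted list in 0. Genes were drawn independently of each other there, and a call was an unadjusted camera p under 0.05. In the data the 4 lists called below had estimated correlations between 0.143 and 0.535, so the simulated rates for lists do not carry over to them. The alternatives were the replicate number as a block, each array left out in turn, quantile normalization, median centring, cyclic loess, only the brighter probe sets, an intensity trend with robust variances, array weights, the mean of all probe sets of a gene, the Y-linked level as a covariate, sex-linked and sex-biased genes left out, the estimated correlation, fry, a t statistic without moderation, and folds of 1.2 and 2.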

Results

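The liver transcriptome of adult offspring was compared by paternal treatment. Males were made hyperglycaemic with streptozotocin, or received citrate buffer alone, and were then bred with healthy females; 3 offspring livers per group (STZ-O and CB-O) were each measured on 1 array. The stated interest of the series was metabolism of the progeny, lipid metabolism in particular. Any 2 arrays correlated across probe sets at a Pearson r of 0.991 to 0.994, so the differences described here are small beside the range of expression among genes. In a principal component analysis the leading component held 27.6% of the variance and did not separate the groups: STZ-O replicate 3 lay at 17.5 and CB-O replicate 1 at -14.1, with the other 4 arrays between them. On the next component (22.2%) the STZ-O arrays lay at -13.0, -2.66 and -1.99, all below the CB-O arrays, the lowest of which lay at -0.846.

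In offspring of hyperglycaemic fathers, genes of the interferon response stood higher as a list, as did genes of fatty acid and triglyceride synthesis and of the unfolded protein response, and markers of sinusoidal endothelium stood lower. These calls rest on camera at its preset correlation. With an estimated correlation 0 lists passed, and the adjusted p was 0.824 for all 4. Of the 10 ways of parting the 6 arrays 3 against 3, the real one included, 9 gave at least 4 calls at the preset correlation. The endothelial shift rested on STZ-O replicate 3, without which its median was 0.014. The fatty acid and triglyceride call was lost without CB-O replicate 3 (camera adjusted p = 0.222, median 0.036). The unfolded protein call was lost in 3 of the 6 fits with 1 array left out. The shifts were modest, with list medians between -0.161 and 0.202 on the log2 scale. No single gene passed the adjusted threshold. In limma, 0 of 22093 genes had an adjusted p under 0.05, the smallest being 0.0789, while 1255 (5.68%) had an unadjusted p under 0.05, 706 higher and 549 lower in STZ-O. Over all 68842 probe sets 0 passed, both in limma (3678 at an unadjusted p under 0.05) and with a t statistic without moderation. At an unadjusted p under 0.05 and a fold of at least 1.5 there were 41 genes, 29 higher and 12 lower. The 3 arrays of one group lay entirely above or below those of the other for 10.1% of genes, where chance gives 10%. Of 143 genes named by the fixed rule, 79 moved by over 1.5 times or changed sign with 1 array left out, 37 of them without STZ-O replicate 3. The left-out values are printed below for some of these genes only.

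The genes ranked highest by moderated t included Apol3l1, a member of the apolipoprotein L family, and Egr1, an immediate early transcription factor. Apol3l1 was at 7.33 ± 0.12 (SD, n = 3) in STZ-O and 6.48 ± 0.10 (SD, n = 3) in CB-O, a difference of 0.86 ± 0.08 (SE), or 1.81-fold, with a limma adjusted p of 0.0789. Egr1 was 0.74 ± 0.07 higher (1.67-fold, limma adjusted p = 0.0789). Both passed in 2 of 16 settings, with the dimmer probe sets left out (adjusted p = 0.0393) and with an intensity trend and robust variances (adjusted p = 0.0372). Adjusted over probe sets both were at 0.286, and the highest adjusted p over genes was 0.433, without CB-O replicate 3. The antiviral GTPase Mx2 differed by 0.69 ± 0.10 (adjusted p = 0.286) and the interferon-linked Ifi27l2b by 0.73 ± 0.16 (adjusted p = 0.532). Gckr, which encodes the regulatory protein that holds glucokinase in the nucleus, differed by 0.61 ± 0.11 (1.53-fold, adjusted p = 0.504). Nr0b2, which encodes the bile acid-responsive repressor SHP, differed by 0.81 ± 0.17, and Avpr1a, the hepatic vasopressin receptor gene, by 1.08 ± 0.25 (2.11-fold). The transcription factor gene Zbtb16 differed by 1.07 ± 0.28 (0.69 without CB-O replicate 1), and Paqr9, Adh6 and AKR1C3l1 by 0.64, 0.84 and 0.65. Of these genes all 3 STZ-O arrays lay above all 3 CB-O arrays, and none of the differences passed the adjustment. Ranking by t, for the highest and the lowest genes alike, favours genes whose groups part, so the parting adds no evidence.

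Among the genes ranked lowest in STZ-O, Plaat1, which encodes a phospholipase and acyltransferase, differed by -1.15 ± 0.23 (SE, 2.21-fold, limma adjusted p = 0.517); without STZ-O replicate 2 its adjusted p was 0.0255. Inmt, an N-methyltransferase gene, was at 6.81 ± 0.13 against 7.82 ± 0.47, a difference of -1.01 ± 0.21. The retinol dehydrogenase gene Rdh16 differed by -0.63 ± 0.14 and Ooep by -1.24 ± 0.31, with all 3 STZ-O arrays below all CB-O arrays in each case. Nrg4, which encodes a secreted growth factor of the neuregulin family, differed by -0.68 ± 0.24, and Apof, which encodes a lipid transfer inhibitor of lipoproteins, by -0.79 ± 0.27. The values for the cytochrome P450 genes Cyp1a1 and Cyp17a1 were -0.83 ± 0.28 and -0.61 ± 0.29, and those for Sult1c2 and Serpina3m were -0.60 ± 0.23 and -0.75 ± 0.37. With 1 array left out, Cyp1a1 was at -0.55 (without STZ-O replicate 1), Nrg4 at -0.42 (without STZ-O replicate 2), Sult1c2 at -0.33 (without CB-O replicate 2), Cyp17a1 at -0.35 and Serpina3m at -1.21 (both without STZ-O replicate 3). For Cyp1a1, Apof, Sult1c2, Cyp17a1 and Serpina3m the arrays of both groups overlapped, and adjusted p-values in this set ranged from 0.517 to 0.908. Apol3l1, Egr1, Mx2, Ifi27l2b, Nr0b2, Plaat1, Inmt, Ooep, Cyp1a1 and Cyp17a1 averaged below 8.26, the 95th percentile of negative controls, as did the list members Mx1, Irf7, Scd and Scd2; 72 of the 143 named genes did so. Of these 72, 7 averaged below the negative control median of 5.51, among them Fabp4, Il6 and Lum, for which no difference is given.

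**Figure D1:**
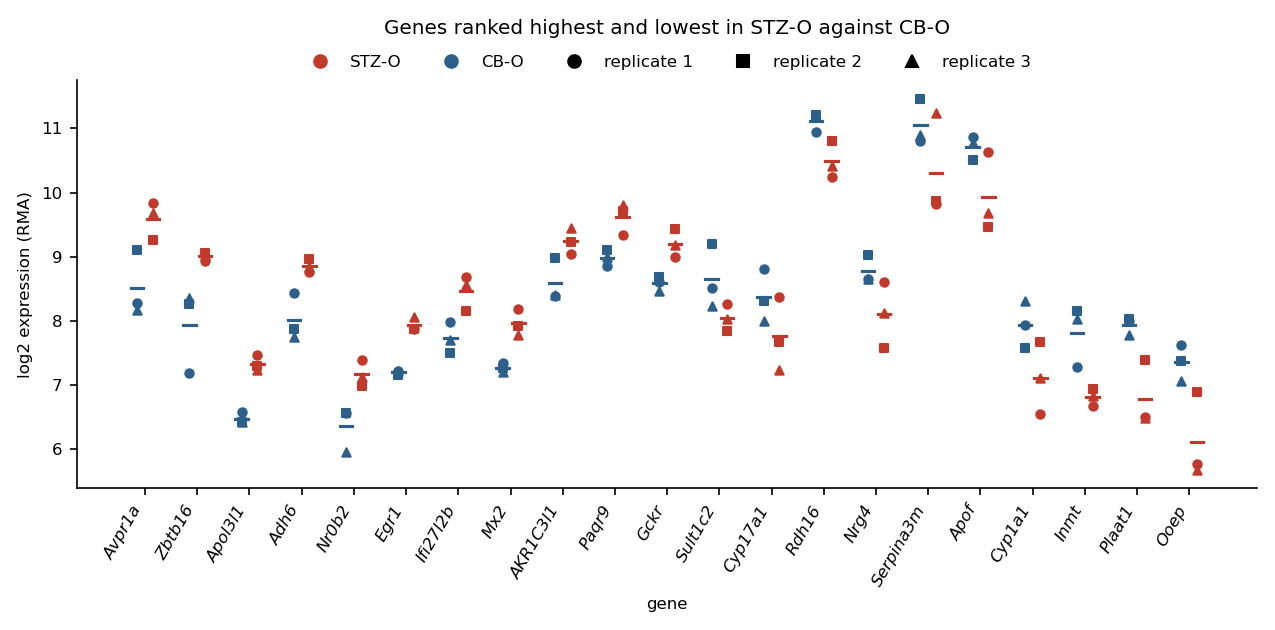
Log2 expression (RMA) on the vertical axis of the genes ranked highest and lowest in STZ-O against CB-O, provisional symbols left out, with 1 point per array (red, STZ-O; blue, CB-O; shapes give the replicate number) and a bar at each group mean. The 3 STZ-O arrays lie above the 3 CB-O arrays for Apol3l1 and Egr1, and the groups overlap for Serpina3m and Cyp17a1.

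Genes of fatty acid and triglyceride synthesis were higher in STZ-O as a list. Camera gave an adjusted p of 0.000137 for the list at the preset correlation; with an estimated correlation p = 0.167 (adjusted p = 0.824), so the call was lost. Of 23 measured members 20 were higher and 3 lower, with a median difference of 0.15, and 6 had an unadjusted p under 0.05, all higher; 0 passed when adjusted over the list alone and 0 over all genes in limma. The stearoyl-CoA desaturase genes Scd and Scd2 differed by 0.55 ± 0.18 and 0.26 ± 0.06 (SE). Lpin1, which encodes the phosphatidate phosphatase lipin 1, differed by 0.77 ± 0.23, and Acaca, the acetyl-CoA carboxylase gene that makes malonyl-CoA, by 0.27 ± 0.10. Other core genes of the pathway, chosen after their values were seen, were closer to 0: Fasn at 0.18 ± 0.20 and the regulators Srebf1 and Mlxipl at 0.01 ± 0.11 and -0.18 ± 0.17. Without CB-O replicate 3, whose level for the list was the lowest of the 6 at -0.292, camera's adjusted p was 0.222 and the list median 0.036; Scd was then at 0.36. Acaca was at 0.15 without STZ-O replicate 2.

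The other lipid lists did not pass. Cholesterol synthesis and sterol response had 16 of 19 members lower in STZ-O and 3 higher, a median of -0.044, 0 members at an unadjusted p under 0.05 in limma and 0 when adjusted over the list alone (camera adjusted p = 0.268, Down). Its members with the smallest p were Insig1 at 0.37 ± 0.23, Msmo1 at -0.41 ± 0.29, Sqle at -0.41 ± 0.31 and Hsd17b7 at -0.34 ± 0.26. Without STZ-O replicate 3 they were at 0.63, -0.07, -0.05 and -0.08. The list's level spread from 0.380 in CB-O replicate 1 to -0.405 in STZ-O replicate 3. It passed as lower without STZ-O replicate 1 (camera adjusted p = 0.0127) and without CB-O replicate 3 (0.0155); its direction was Up without STZ-O replicate 3 (adjusted p = 0.175) or CB-O replicate 1 (0.283).

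Within fatty acid oxidation and ketogenesis, 14 of 25 members were higher and 11 lower, with a median of 0.027 (camera adjusted p = 0.492). Ppara, the nuclear receptor that drives fatty acid catabolism, and Cpt2, a carnitine palmitoyltransferase of the inner mitochondrial membrane, passed when adjusted over the list alone, 2 genes against 0 over all genes (4 at an unadjusted p under 0.05). They went opposite ways, Ppara rising by 0.47 ± 0.11 (SE) and Cpt2 differing by -0.26 ± 0.06. Cpt1a, the entry step of mitochondrial oxidation, was at -0.40 ± 0.17 (-0.24 without CB-O replicate 1 and -0.61 without CB-O replicate 2). The microsomal fatty acid hydroxylase gene Cyp4a2 was at 0.29 ± 0.12 (0.19 without STZ-O replicate 1). The level of the list was higher on all 3 STZ-O arrays than on any CB-O array (exact permutation p = 0.1, the smallest possible). Of the 31 lists 2 reached that p, where chance gives 10% of lists.

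Among lipoprotein assembly, lipid uptake and lipid droplet genes 17 of 35 were higher and 18 lower. The median of -0.018 and the direction of camera (Down, adjusted p = 0.847) differed in sign from the mean of 0.017. Cidea, a lipid droplet protein gene, fell by 0.45 ± 0.09 (SE) and was the 1 gene that passed when adjusted over the list alone; 0 passed over all genes, with 5 at an unadjusted p under 0.05. Fabp2 and Mttp, which encode a fatty acid binding protein and the microsomal triglyceride transfer protein, were at 0.63 ± 0.23 and 0.19 ± 0.07; Fabp2 was at 0.34 without STZ-O replicate 1. Camera's direction for this list was Up without STZ-O replicate 3, CB-O replicate 1 or CB-O replicate 2 (adjusted p = 0.963, 0.779 and 0.925). In the bile acid and sterol transport list, 12 of 20 were higher and 8 lower (median 0.022, camera adjusted p = 0.265). There 3 genes passed when adjusted over the list alone and 0 over all genes (4 at an unadjusted p under 0.05): Nr0b2, Abcc2 (0.35 ± 0.06), a canalicular export pump, and Abcg5 (-0.45 ± 0.10), a sterol exporter subunit. Slco1b2, an uptake transporter, was at 0.22 ± 0.07. Fry's mixed test, which asks for change in either direction, gave this list alone of the 31 an adjusted p under 0.05 (0.0214).

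The interferon response list gave the smallest camera p of the 31 lists, with an adjusted p of 2.78e-08 at the preset correlation. With an estimated correlation p = 0.0804 (adjusted p = 0.824), so the call was lost. Of 18 measured members 15 were higher in STZ-O and 3 lower, with a median difference of 0.20, and 8 had an unadjusted p under 0.05, all higher. When adjusted over the list alone 6 genes passed, against 0 over all genes in limma. They were Mx2, Psmb8, Mx1 and Irf7, with Irf9 and Usp18 chosen after their values were seen. The immunoproteasome subunit gene Psmb8 rose by 0.49 ± 0.10 (SE), from 8.40 ± 0.10 (SD, n = 3) in CB-O to 8.89 ± 0.19 (SD, n = 3) in STZ-O. Mx1, another antiviral GTPase gene, rose by 0.39 ± 0.11. Irf7 and Irf9, transcription factors of the response, rose by 0.51 ± 0.15 and 0.21 ± 0.06, and Usp18, which encodes a protease that removes ISG15, by 0.58 ± 0.18. The members that were lower, also chosen after their values were seen, were Ifit2 at -0.20 ± 0.10, Stat2 at -0.04 ± 0.15 and Tap1 at -0.002 ± 0.07. The list level was 0.329, 0.064 and 0.020 on the STZ-O arrays and -0.022, -0.204 and -0.186 on the CB-O arrays. The exact permutation p was 0.1, the smallest possible, which 2 of the 31 lists reached where chance gives 10% of lists. Leukocyte and macrophage markers, as 1 pool of 26 genes, had a median difference of 0.011, or 0.098 without STZ-O replicate 3. In that fit the Kupffer and macrophage list alone had a median of 0.213, as did the interferon list. On all arrays the Kupffer and macrophage median was 0.030.

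The unfolded protein response list, the genes that answer misfolded protein in the endoplasmic reticulum, had 14 of 19 members higher and 5 lower, with a median of 0.15. Camera's adjusted p was 0.0103; with an estimated correlation p = 0.131 (adjusted p = 0.824), so the call was lost. Herpud1, a component of protein degradation at that membrane, was at 0.30 ± 0.10 (SE), the disulphide isomerase gene Pdia6 at 0.23 ± 0.09 (0.13 without CB-O replicate 1), the sensor gene Ern1 at 0.17 ± 0.07 and the transcription factor gene Ddit3 at 0.15 ± 0.05. In all, 5 members had an unadjusted p under 0.05, 0 passed when adjusted over the list alone and 0 over all genes in limma. Xbp1, the target of Ern1, and the chaperone gene Hspa5, chosen after their values were seen, were at -0.30 ± 0.17 and 0.06 ± 0.10. The call was also lost without STZ-O replicate 1 (adjusted p = 0.0506, median 0.113), STZ-O replicate 2 (0.146, median 0.119) or CB-O replicate 2 (0.0664, median 0.145), and with the Y-linked level as a covariate (0.0521, median unchanged).

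Sinusoidal endothelial markers were lower in STZ-O, 11 of 12 members with a median of -0.161. Camera's adjusted p was 0.0256; with an estimated correlation p = 0.304 (adjusted p = 0.824), so the call was lost. The scavenger receptor gene Stab2 was at -0.18 ± 0.07 (SE), the VEGF receptor gene Kdr at -0.41 ± 0.21, Tek at -0.15 ± 0.09 and the Fc receptor gene Fcgr2b at -0.25 ± 0.18. Of the members 1 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone or over all genes in limma. The list level on STZ-O replicate 3 was -0.386, against 0.082 and 0.073 on the other STZ-O arrays. Without that array the median was 0.014 and camera's adjusted p 0.963, with its direction still Down; Stab2, Kdr and Fcgr2b were then at -0.11, -0.19 and -0.02, and Tek at -0.09 (-0.07 without CB-O replicate 2). The adjusted p was 0.178 without CB-O replicate 1 (median -0.068), 0.0562 without CB-O replicate 2 (median -0.197) and 0.0732 with array weights (median -0.119). Camera at the preset correlation called 4 of the 31 lists here, and of the 10 ways of parting the 6 arrays 3 against 3, 9 gave at least as many calls. With an estimated correlation 0 lists passed, and with fry 0 (smallest adjusted p = 0.903).

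**Figure D2:**
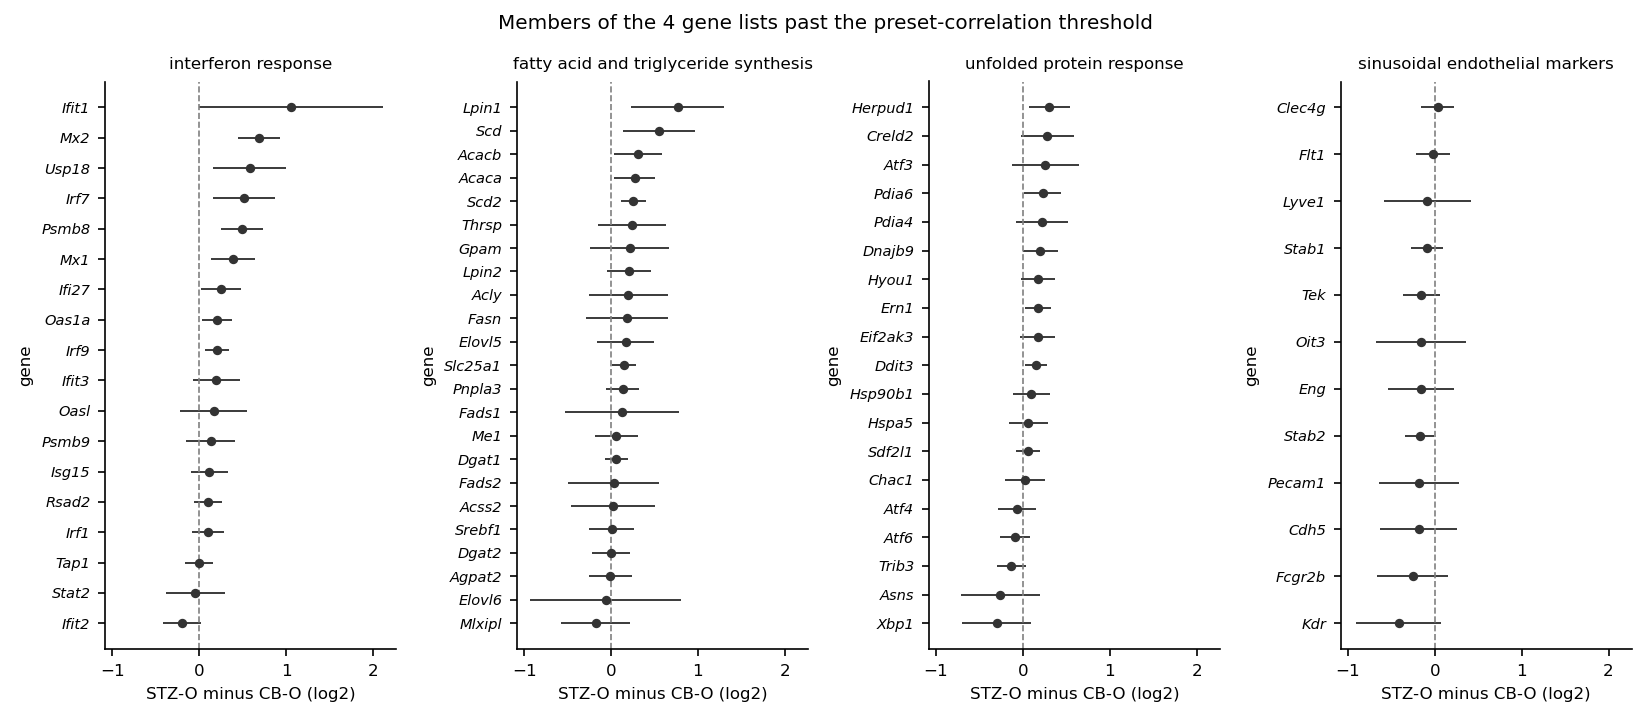
Difference of STZ-O minus CB-O (log2, horizontal axis) for every measured member of the 4 lists called by camera at the preset correlation; points are limma estimates and lines their 95% confidence intervals. Of the interferon response list 15 of 18 members lie above 0, and of the sinusoidal endothelial list 11 of 12 lie below 0.

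**Figure D3:**
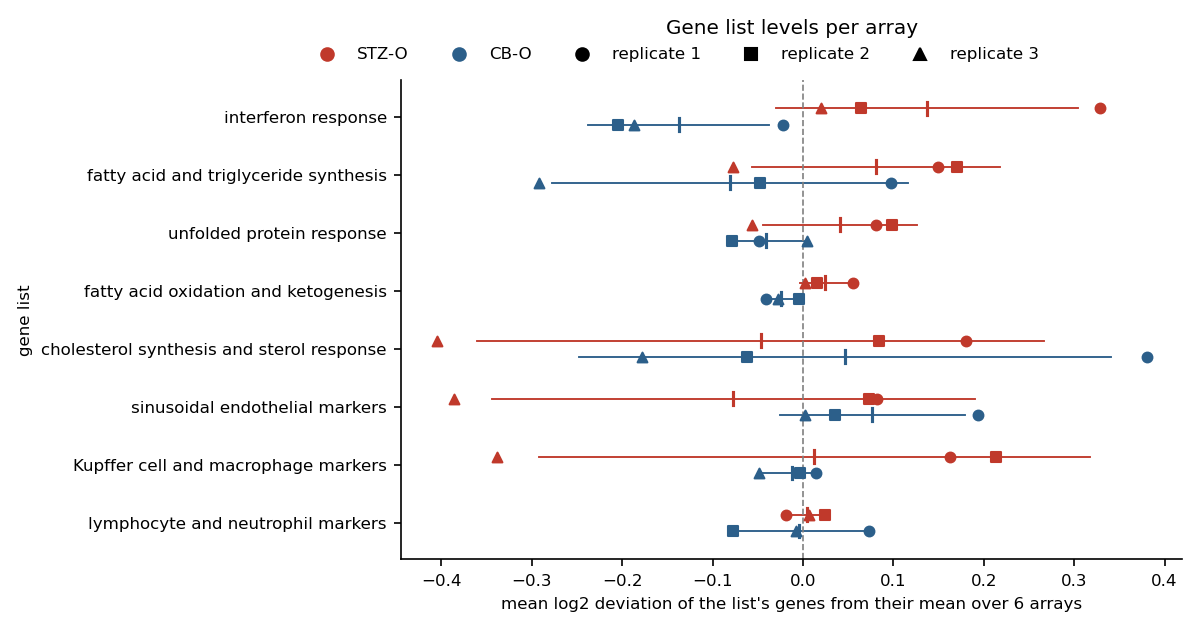
Level of 8 gene lists per array, as the mean log2 deviation of a list's genes from their mean over 6 arrays (horizontal axis; red, STZ-O; blue, CB-O; shapes give the replicate number), with group mean and SD. The groups part for the interferon response and for fatty acid oxidation, the only 2 of all 31 lists to do so, where chance gives 10%. STZ-O replicate 3 is the lowest array for the cholesterol, endothelial and Kupffer lists.

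Lists of glucose handling did not pass on all 6 arrays. In glycolysis and hexose entry, 10 of 16 members were higher (median 0.031, camera adjusted p = 0.111); Gckr was the 1 gene to pass when adjusted over the list alone, against 0 over all genes (2 at an unadjusted p under 0.05). Pklr, the liver pyruvate kinase gene, was at 0.35 ± 0.10 (SE), and Pfkfb1 and Pgam1 at 0.15 ± 0.10 and -0.10 ± 0.07. Without STZ-O replicate 3 this list passed at the preset correlation, with a camera adjusted p of 0.00138 and a median of 0.096. Pfkfb1 and Pgam1 were then at 0.25 and -0.04. With an estimated correlation, on all 6 arrays, the list's adjusted p was 0.824. In gluconeogenesis and glycogen, 11 of 17 were higher (median 0.080, adjusted p = 0.293); without CB-O replicate 3 the direction was Down (median -0.015, adjusted p = 0.925). There the glycogen phosphorylase gene Pygl was at 0.28 ± 0.07 and the pyruvate carboxylase gene Pc at 0.16 ± 0.06. The glycogen branching gene Gbe1 was at 0.23 ± 0.11 (0.14 without STZ-O replicate 3). Ppp1r3g, a glycogen-targeting phosphatase subunit, was at -0.21 ± 0.06. Insulin and growth hormone signalling had 17 of 22 higher (median 0.041, adjusted p = 0.268), with Igf1 at 0.19 ± 0.05, Ghr at 0.13 ± 0.07, Igfbp2 at -0.33 ± 0.08 and Trib3 at -0.13 ± 0.07. In these last lists 0 genes passed when adjusted over the list alone and 0 over all genes in limma, with 3 and 2 at an unadjusted p under 0.05.

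Stress lists other than the interferon and unfolded protein lists did not pass, and 0 of their genes passed when adjusted over the list alone or over all genes in limma. Acute phase and inflammation had 8 of 21 higher and 13 lower (median -0.021, camera adjusted p = 0.268, 1 at an unadjusted p under 0.05), with Hp, the haptoglobin gene, at -0.15 ± 0.06 (SE), Crp at 0.14 ± 0.06 and Orm1 at -0.19 ± 0.09. It passed without CB-O replicate 2 (adjusted p = 0.0402). Oxidative stress and glutathione genes had a median of -0.019 (8 higher, 12 lower, adjusted p = 0.853, 0 at an unadjusted p under 0.05); Gclm was at -0.14 ± 0.09 and Gsta1 at 0.11 ± 0.07. Camera's direction for it was Up without STZ-O replicate 3 or CB-O replicate 2 (adjusted p = 0.963 and 0.332). Xenobiotic metabolism had a median of 0.0038 but a mean of -0.033 and a Down direction in camera (adjusted p = 0.730, 2 at an unadjusted p under 0.05), with the dioxin receptor gene Ahr at 0.38 ± 0.15 (0.19 without STZ-O replicate 3) and its targets Cyp1a1 and Cyp1a2 at -0.83 ± 0.28 and -0.18 ± 0.09; its direction was Up without STZ-O replicate 1 or CB-O replicate 2 (adjusted p = 0.818 and 0.701).

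Enzymes of DNA methylation and histone modification had 10 of 19 higher and 9 lower with a median of 0.0004 (camera adjusted p = 0.899, Up, and Down under quantile normalization and cyclic loess); Mbd2 was at 0.12 ± 0.06 (SE) and Sirt1 at 0.11 ± 0.07. Imprinted genes had 6 of 17 higher and 11 lower (median -0.010, adjusted p = 0.853), with Meg3 at -0.13 ± 0.07 and Nnat at 0.10 ± 0.05. Peg3 was at 0.18 ± 0.12 (0.08 without CB-O replicate 3 and 0.29 without CB-O replicate 1). Both lists changed direction without STZ-O replicate 3 (adjusted p = 0.963 for each), the former also without CB-O replicate 3 (0.954) and the latter without CB-O replicate 1 (0.847). In both lists 0 genes had an unadjusted p under 0.05 in limma and 0 passed when adjusted over the list alone.

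Clock genes had 11 of 17 higher and 6 lower (median 0.046, camera adjusted p = 0.217, 4 at an unadjusted p under 0.05); without CB-O replicate 3 the direction was Down (median -0.026, adjusted p = 0.825). Bmal1 was at 0.31 ± 0.11 (SE), Nr1d2 at 0.15 ± 0.05, Bhlhe40 at 0.18 ± 0.06 and the repressor gene Cry1 at -0.24 ± 0.09; 0 passed when adjusted over the list alone. Of the immediate early genes Egr1 alone passed when adjusted over the list alone, against 0 over all genes (1 at an unadjusted p under 0.05), and the list had a median of 0.017 (adjusted p = 0.184); Junb, Atf3 and Zfp36 were at 0.28 ± 0.15, 0.26 ± 0.17 and -0.07 ± 0.07. The list passed without STZ-O replicate 1 (adjusted p = 0.0388). Without STZ-O replicate 3 its direction was Down (adjusted p = 0.747), with Junb at 0.11 and Atf3 at 0.04. Medians of ribosomal protein, oxidative phosphorylation and cell cycle genes were 0.039, 0.031 and 0.035 (camera adjusted p = 0.111, 0.178 and 0.111), with 0, 0 and 1 gene at an unadjusted p under 0.05 and 0 passing when adjusted over the list alone. The proliferation marker Mki67 was at 0.22 ± 0.09, Rpl19 at 0.10 ± 0.05 and Ndufb8 at 0.14 ± 0.07. Without STZ-O replicate 3 or CB-O replicate 2 the ribosomal list passed (adjusted p = 0.00815 and 0.0252), as did oxidative phosphorylation (0.0320 and 0.0252), and the cell cycle list passed without STZ-O replicate 1 (0.0383).

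Markers of liver cell types other than endothelium gave no list call. The endothelial call was itself lost with an estimated correlation (adjusted p = 0.824) and without STZ-O replicate 3 (0.963). Hepatocyte markers had 7 of 10 members lower (median -0.061, camera adjusted p = 0.111): the urea cycle gene Ass1 fell by 0.34 ± 0.08 (SE) and was the 1 gene to pass when adjusted over the list alone, against 0 over all genes (2 at an unadjusted p under 0.05), while Serpina1 was at -0.38 ± 0.11 and Hnf4a at -0.19 ± 0.11. That list passed without CB-O replicate 3 (adjusted p = 0.0225). Red cell markers had 6 of 8 lower (median -0.144, adjusted p = 0.0858), with Hba-a1 at -0.27 ± 0.15 and Hbb-b1 at -0.20 ± 0.11; they passed with the dimmer probe sets left out (0.00496), with array weights (0.0499), without STZ-O replicate 3 (0.000606) and without CB-O replicate 3 (0.0207). Without CB-O replicate 1 their adjusted p was 0.344, with Hba-a1 at -0.09, and with an estimated correlation 0.824. Kupffer cell and macrophage markers had 9 of 12 higher (median 0.030, adjusted p = 0.612), with Adgre1 at 0.18 ± 0.14 and Csf1r at -0.13 ± 0.18. Without STZ-O replicate 3 their median was 0.213 and the adjusted p 4.52e-07 at the preset correlation. With an estimated correlation, on all 6 arrays, camera's adjusted p was 0.953. The level of this list on STZ-O replicate 3 was -0.338, against 0.162 and 0.213 on the other STZ-O arrays. The direction was Down without STZ-O replicate 1 (adjusted p = 0.825) or 2 (0.560).

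Lymphocyte and neutrophil markers were split 7 and 7, with a median of -0.012, a mean of 0.0084 and an Up direction in camera (adjusted p = 0.832). The leukocyte gene Ptprc was at 0.32 ± 0.08 (SE) and Prf1, a cytotoxic cell gene, at 0.21 ± 0.08. Stellate cell and fibroblast markers had a median of -0.006 (adjusted p = 0.706), with Dcn at -0.13 ± 0.14 (-0.004 without STZ-O replicate 2 and -0.27 without STZ-O replicate 3). Cholangiocyte markers had a median of 0.0009 but a mean of -0.0078 and a Down direction (adjusted p = 0.899), with Epcam at 0.11 ± 0.06 and Cldn4 at -0.13 ± 0.10. Markers of adipocytes, pancreas and muscle had a median of -0.019 and a Down direction with a mean of 0.0008 (adjusted p = 0.899; Up under cyclic loess), with Lep at 0.26 ± 0.10 and Prss1 at -0.08 ± 0.08. Each of these 4 lists changed direction in 1 or more fits with 1 array left out, at adjusted p-values of 0.347 or more. In the lymphocyte, Kupffer, red cell, stellate, cholangiocyte and adipocyte lists 0 genes passed when adjusted over the list alone or over all genes in limma, with 2, 0, 0, 0, 0 and 1 at an unadjusted p under 0.05.

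Signal for Y-linked genes and for the male-biased Cyp2c11, Cyp2c13, Cyp3a2 and Hsd3b5 was similar on all 6 arrays. The labels do not give the sex of the animals. Of the other male-biased genes, C6 differed by 0.40 (0.22 without CB-O replicate 2) and Cyp3a18 by -0.21 (-0.11 without STZ-O replicate 1). Over the 6 arrays Ddx3y ranged from 9.22 to 9.67, Eif2s3y from 8.38 to 8.67, Kdm5d from 7.59 to 7.75 and the male-specific cytochrome gene Cyp2c11 from 11.8 to 12.1. Kdm5d lay below the 95th percentile of negative controls, and Sry (5.40 to 5.70) and Usp9y (3.37 to 3.48) lay near or below their median of 5.51. The Y-linked list had a median difference of 0.0099, a mean of -2.8e-05 and an Up direction in camera (adjusted p = 0.899), which was Down under quantile normalization and cyclic loess, and the male-biased list a median of 0.016 (adjusted p = 0.944); both also turned Down in 3 of the 6 fits with 1 array left out. Female-biased genes had 5 of 8 higher (median 0.148, adjusted p = 0.113), with Cyp2c7 at 0.21 ± 0.07 (SE) and Prlr, the prolactin receptor gene, at 0.85 ± 0.33. Without STZ-O replicate 1 the difference for Prlr was 0.43. These female-biased genes were less even between arrays. Cyp2c12 ranged from 9.04 on CB-O replicate 1 to 10.52 on STZ-O replicate 2, and Prlr from 5.44 on CB-O replicate 3 to 7.41 on STZ-O replicate 1. The list passed without STZ-O replicate 3 (adjusted p = 0.0128). In the 3 sex lists 0 genes passed when adjusted over the list alone in limma, with 0, 0 and 2 at an unadjusted p under 0.05.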

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

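No alternative was added after the results were seen. The cause of the changes reported here was not tested, beyond fewer arrays in the fits that leave 1 out and fewer genes where dim probe sets were left out. Adjusted p-values are limma's for genes and camera's for lists unless fry is named. The interferon response list stayed higher and past the threshold under each scaling, filter, weight, covariate and left-out array. It lost its call with an estimated correlation and with fry. The variance models were applied to genes and probe sets and not to lists. Scaling moved the median difference of all genes by less than 0.01: it was -0.0037 as analysed and -0.0060, 0.0030 and -0.0037 under quantile normalization, median centring and cyclic loess. Dim signal is a limit throughout, with negative controls at a median of 5.51 and a 95th percentile of 8.26.

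With an estimated correlation 0 lists passed, and the adjusted p was 0.824 for the fatty acid and triglyceride synthesis, interferon, unfolded protein and endothelial lists. With fry 0 lists passed, with an adjusted p of 0.903 for fatty acid synthesis, interferon and the unfolded protein response and 0.925 for the endothelial list; the male-biased list reversed (0.993). With dim probe sets left out 2 genes passed, Apol3l1 and Egr1, and the DNA methylation (0.783) and male-biased (0.901) lists reversed. With an intensity trend and robust variances the same 2 genes passed. Array weights, lowest at 0.775 for STZ-O replicate 3, gave 0.0732 for the endothelial list and reversed the male-biased list (0.940). The Y-linked level as a covariate gave 0.0521 for the unfolded protein response. That level spanned only 7.09 to 7.20 over the arrays, so this fit is no adjustment for sex. Quantile normalization and cyclic loess reversed the DNA methylation and Y-linked lists (0.987 and 0.982 for both), and cyclic loess the adipocyte, pancreas and muscle list (0.995). Genes at an unadjusted p under 0.05 numbered 453 at a fold of at least 1.2 and 10 at a fold of at least 2, against 41 at 1.5. Of those 41 genes, 28 to 41 were shared with each alternative.

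The labels number the replicates 1 to 3 in both groups. Deviations of same-numbered arrays from their group means correlated at 0.051, -0.099 and 0.009 across probe sets, so the numbers were not taken to pair animals, and arrays did not each correlate best with their own number. With the replicate block 0 genes passed and 5 lists did; cholesterol synthesis and sterol response passed as lower (adjusted p = 0.0420), and no other call changed.

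Leaving out 1 array in turn gave 0 to 1 probe sets past the threshold (1 without CB-O replicate 2), 0 to 1 genes (Plaat1, without STZ-O replicate 2) and 3 to 9 lists (9 without STZ-O replicate 3). The adjusted p ranged from 3.31e-08 to 0.222 for fatty acid and triglyceride synthesis, 2.12e-11 to 0.000149 for interferon, 6.67e-06 to 0.146 for the unfolded protein response, 0.00128 to 0.963 for endothelial markers, 0.0127 to 0.283 for cholesterol synthesis and 0.222 to 0.963 for lipoproteins. The last 2 reversed in some of these fits. Further lists reversed in 1 to 3 of the 6 fits, and no list that reversed passed there (smallest adjusted p 0.175). Over all 6 fits, reversed or not, the adjusted p ran from 0.0664 to 0.925 for gluconeogenesis, 0.270 to 0.963 for oxidative stress, 0.347 to 0.818 for xenobiotic metabolism, 0.630 to 0.985 for DNA methylation, 0.560 to 0.963 for imprinted genes and 0.332 to 0.963 for Y-linked genes. The ranges over all 6 fits were 0.470 to 0.979 for male-biased genes, 0.0613 to 0.825 for the clock, 0.0388 to 0.747 for immediate early genes, 4.52e-07 to 0.825 for Kupffer cells, 0.222 to 0.892 for stellate cells, 0.443 to 0.971 for cholangiocytes, 0.391 to 0.963 for lymphocytes and 0.147 to 0.972 for adipocyte, pancreas and muscle markers. Genes that reversed, with the range of their log2 difference, were Cd5l (-0.0173 to 0.371), Csf1r (-0.253 to 0.0929), Cyp2c11 (-0.0598 to 0.0964), Eif2s3y (-0.0125 to 0.134), Pdgfrb (-0.0814 to 0.0140) and Usp9y (-0.000882 to 0.0469).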

Other observations

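The immune cell test (its rule was tightened after its value was known), the clock test and the 1-array test of the endothelial list were chosen after the results were seen, and so were all genes named in the next paragraph; the other tests were fixed before their values were seen, except that 1 gene of the lipogenic test, Pmvk, had been in the cholesterol list.

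Some genes outside the lists were chosen after their values were seen, so they show nothing about their families as a whole. Bst2, which encodes the antiviral tether tetherin, was at 10.19 ± 0.06 (SD, n = 3) against 9.67 ± 0.08 (SD, n = 3), a difference of 0.52 ± 0.07 (SE, limma adjusted p = 0.225). Herc6 differed by 0.79 ± 0.11, Ifi44 by 0.26 ± 0.07, Ifi44l by 0.61 ± 0.18 and the class I genes RT1-S3 and RT1-N2 by 0.56 ± 0.11 and 0.81 ± 0.23, whereas RT1-A was at 0.05 ± 0.19. Among alcohol dehydrogenase and aldo-keto reductase genes Adh4 was 2.29-fold higher in STZ-O, and Akr1c1 differed by 0.63 ± 0.19 and Akr1c2 by 0.61 ± 0.20, while Adh7 and Adh1c were at -0.39 ± 0.09 and -0.27 ± 0.06. Slc2a12, a glucose transporter gene, differed by 1.04 ± 0.17 (adjusted p = 0.322), Nrcam by 0.77 ± 0.09 and Arrdc3 by 0.55 ± 0.08. Hsd11b1, which regenerates active glucocorticoid, was at -0.30 ± 0.05. The metallothionein genes Mt1, Mt2A and Mt1m were at -0.74 ± 0.42, -0.68 ± 0.37 and -0.92 ± 0.46, with overlapping arrays; without STZ-O replicate 3 they were at -0.37, -0.41 and -0.55, and without STZ-O replicate 1 at -1.18, -1.15 and -1.51. Akr1c1 was at 0.42 without CB-O replicate 3 and Akr1c2 at 0.38 without CB-O replicate 1. Each sign in this paragraph was the same under quantile normalization, median centring and cyclic loess and with each array left out, apart from RT1-A (-0.16 without CB-O replicate 1), and no adjusted p here was under 0.05.

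The interferon list kept its call at the preset correlation with each array left out in turn, and lost it with an estimated correlation (p = 0.0804, adjusted p = 0.824). A hypothesis that a wider interferon programme stood higher in STZ-O was put to 27 further genes not looked at before. Of 25 measured, 24 were higher, with a median of 0.108. The camera p was 2.48e-08, though 0.0702 with an estimated correlation, and 1 gene (Samd9l, 0.39 ± 0.08) passed when adjusted over that list alone. These genes came from the same 6 arrays, and members of the first list had an estimated correlation of 0.418. The 24 are therefore neither separate counts nor an independent replication. With each array left out in turn the median of the first interferon list stayed between 0.154 and 0.230, so its median difference did not hang on any 1 array. For that list the highest adjusted p was 0.000149 (without CB-O replicate 3). It is at the preset correlation, so it cannot show whether 1 array carries the call. STZ-O replicate 1 had the highest list level, 0.329 against 0.064 and 0.020 on the other STZ-O arrays. More immune cells in STZ-O livers could also raise these genes. Lymphocyte, neutrophil and macrophage markers, pooled, had a median of 0.01074, but 0.098 without STZ-O replicate 3. The macrophage list alone was then at 0.213, as was the interferon list. Without STZ-O replicate 1 the macrophage list was at -0.029, and without STZ-O replicate 2 at -0.014. This explanation stays open, as do infection or housing, for which the labels give nothing, and paternal hyperglycaemia itself. Of the 10 splits of the 6 arrays 1, the real one, gave a p this small for the list (8.98e-10, next 1.54e-08), and 10 splits are too few for a share under 0.05.

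The fatty acid and triglyceride synthesis list lost its call with an estimated correlation (adjusted p = 0.824) and without CB-O replicate 3 (adjusted p = 0.222), the latter of which is consistent with 1 array carrying the call. A glucose-responsive lipogenic programme was tested on 13 measured genes of a further list and stayed undecided, with a median of 0.06403, a camera p of 0.0206 and p = 0.173 with an estimated correlation (median 0.086 for the 12 genes without Pmvk); Tkt (0.25 ± 0.08) and Klf10 (0.22 ± 0.07) led it. Another time of day at death cannot be told apart from the groups: the labels say that the animals were fed but give neither the hour nor the time since a meal, and the clock list's mixed fry p of 0.4118 decides nothing with 3 arrays per group and a direction that turned without CB-O replicate 3. Of the 10 splits 3 gave a p as small for this list (real 8.81e-06, smallest other 3.02e-11), and a share under 0.05 cannot be reached.

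The lower endothelial markers may reflect 1 liver sample: without STZ-O replicate 3 the adjusted p was 0.9627 (0.824 with all arrays and an estimated correlation), and Kupffer markers were low on the same array. Cell makeup of the sampled piece and a lower yield from that sample were not tested apart. A wider unfolded protein response, tested on 20 further genes, stayed undecided with a median of 0.07902 (camera p = 0.0234, p = 0.416 with an estimated correlation).

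Among the 10 splits of the 6 arrays, the real split gave 0 probe sets and 0 genes past the adjusted threshold (highest other 1 for each). Against a count of 0 all 10 splits must give at least as many, so this comparison decides nothing. It gave 41 genes at an unadjusted p under 0.05 and a fold of at least 1.5, the highest other being 32, so 1 of 10 splits reached that count. For gene lists called by camera at the preset correlation, 9 of 10 splits gave at least the 4 of the real split, and the highest other gave 18. The 1255 genes of the real split at an unadjusted p under 0.05 were exceeded by 3 other splits (highest 1571). With 10 splits no share under 0.05 is possible.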
